A study of Drosophila melanogaster with 2 samples.

How the data were processed

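Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos aged 0 to 24 h that expressed Invected fused to enhanced green fluorescent protein (Inv-eGFP). Invected is a homeodomain transcription factor and the paralog of Engrailed. The antibody was directed against GFP, and chromatin was sonicated to a stated size range of 200 to 800 bp, per the labels. The samples formed 1 group of 2 biological replicates with no second condition, so the comparisons were between replicates, between the peaks and chance, and between gene groups.

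The deposited files were lists of peaks on dm6. Per the labels, peaks were ranked on the irreproducible discovery rate (IDR) and then thresholded. The aligner, the peak caller and their versions are not given in the sources used here. Each replicate had a ranked and a thresholded list. The authors also pooled both replicates into 2 ranked and 2 thresholded lists, the smaller thresholded one being called conservative. The signal value of each peak is the authors' own peak height, relative to a control library per the labels, on a scale that is not stated. It was used only to rank and describe peaks within a list. The score of each peak is the authors' deposited rescaling of the IDR to whole numbers up to 1000, and the lowest score in every thresholded list was 830, which corresponds to an IDR of 0.0100. Read counts were not analysed here, so the depth of the 2 libraries is unknown, and no value could be set against depth. Control libraries were not analysed here.

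The main set was the larger pooled thresholded list, with 3393 of its 3406 peaks on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X. Peaks on other sequences were left out of all tests. The ranked list held 3533 peaks at or above the lowest listed score, 127 more than the thresholded list, for a reason not given in the sources used here. Protein-coding genes (13945) and their transcription start sites (TSS) came from Ensembl release 115, and sequence came from the Release 6 genome. Every peak ended within the length of its arm in that sequence. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

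Peaks were called shared when they overlapped by at least 1 bp, and chance came from 1000 random placements of the replicate 2 intervals on the same arms (one-sided permutation test). The rank agreement of signal values was Spearman's rho across shared peaks, with a 95% interval from 1000 bootstraps of 1 Mb blocks and no p-value, because peaks are not independent replicates. The promoter share was the percentage of summits within 1 kb of a TSS, against 1000 random placements (two-sided permutation test). A gene was counted as holding a summit when one lay in the gene or within 2 kb of it. Each of 21 gene lists was compared with 10000 random lists matched on gene length in 20 bins (two-sided permutation test), with Benjamini-Hochberg adjustment over the lists. Each of 10 words of DNA was counted within 50 bp of the summits and in flanking windows centred 500 bp away on each side. Folds were taken over the mean of both flanks. The exact two-sided McNemar test used only the flank at lower genome coordinates, whatever the strand of the gene. Its p-values had Benjamini-Hochberg adjustment over the words. A fold and the p-value beside it thus rest on different flanks. Summits at the en-inv locus, with 20 kb on either side, were compared with 1000 placements (one-sided), and the X chromosome was compared with the autosomes by an exact two-sided binomial test. The p-values of these tests treat peaks or genes as the units and do not measure variation between embryo collections.

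The tests, lists, words and main alternatives were fixed before the data were examined. So was the rule for the genes named. It took inv and en, the genes nearest the 15 strongest peaks that overlapped a peak of both replicates and of the conservative list, the 5 genes with the most summits, and up to 3 members of each list with the highest signal. Members without a summit were named only in the segment polarity and Engrailed-regulated lists. Older symbols were matched through synonyms, and 1 of the 37 entries of the homeobox list, 1 of the 9 tracheal ones and 1 of the 10 germline ones matched no gene. The alternatives were the conservative list, the upper 50% of peaks by signal, each replicate's own list, other windows, other rules of assignment and other tests. Merged regions, except for peak numbers, and the lower 50% by signal were added after the data were seen. On simulated data, a promoter share of 68.3% was recovered as 68.9%. Of the unchanged lists of long genes, 1.33% were called by the length-matched test and 60.0% by Fisher's exact test without matching. A word expected in 25.2% of simulated windows, placed and chance occurrences together, was found in 25.5%. For the lists, simulated summits were placed at random along the arms, while most real summits lay at promoters. The rates of calls for lists therefore need not hold for these data. For the word, simulated summit and flank windows were random sequence of the same base composition. Differences in composition between summits and flanks were therefore not simulated.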

Results

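Inv-eGFP peaks from 2 biological replicates of 0 to 24 h embryos were described as lists. The main pooled list held 3406 peaks with a median width of 424 bp, which merged into 3116 regions covering 1205 kb. The conservative pooled list held 2554 peaks. Replicate 1 alone gave 2859 peaks and replicate 2 alone gave 2156, a ratio of 1.33. Signal values in the main list had a median of 132 and ran from 2.07 to 3141 in the authors' units. Library depth is unknown.

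The first question was which genes lay at the strongest sites and whether both replicates found them. The strongest peak, with a signal of 3141, lay at 2R 21501693 to 21502238, 79 bp from a TSS of MESK2 and within 1 kb of one of TAF1C-like. The next lay at 3R 30046036 to 30046499, 66 bp from the TSS of RpL32, a protein of the large ribosomal subunit, with a signal of 2224. RhoGAP93B on 3R followed at 1966, and Rpn6 on 2R, a subunit of the proteasome lid, at 1930. All 15 of the strongest shared peaks lay at promoters, and their remaining genes were Mic26-27, Daxx, jagn, CG8613, Pp2A-29B, Capr, Pym, Sec61beta, CG11857, Sumo and Jwa, with signals from 1797 at Mic26-27 to 1412 at Jwa. Sumo encodes the small ubiquitin-related modifier, and Sec61beta encodes a subunit of the translocon of the endoplasmic reticulum. At 6 of the 15 sites a TSS of another gene also lay within 1 kb.

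Of the 2129 replicate 2 peaks on the arms, 1712 (80.4%) overlapped a replicate 1 peak, against 1.36% by chance (one-sided permutation p = 0.001, the smallest that 1000 placements can give). In the other direction 1688 of 2858 peaks (59.1%) were shared. Across these 1688 peaks, the signal values of the replicates had a Spearman rho of 0.681 (95% block bootstrap interval 0.651 to 0.708). Among the 100 strongest main-set peaks, 100 overlapped a peak of each replicate, and in the full main set 1714 did (50.5%), while 1148 overlapped a peak of 1 replicate and 531 of neither. With summits within 100 bp taken as shared, rho was 0.765. The chance level of 1.36% came from placements spread evenly over the arms, although most peaks of both lists lay at promoters. It therefore does not separate shared sites from a shared preference for promoters.

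**Figure D1:**
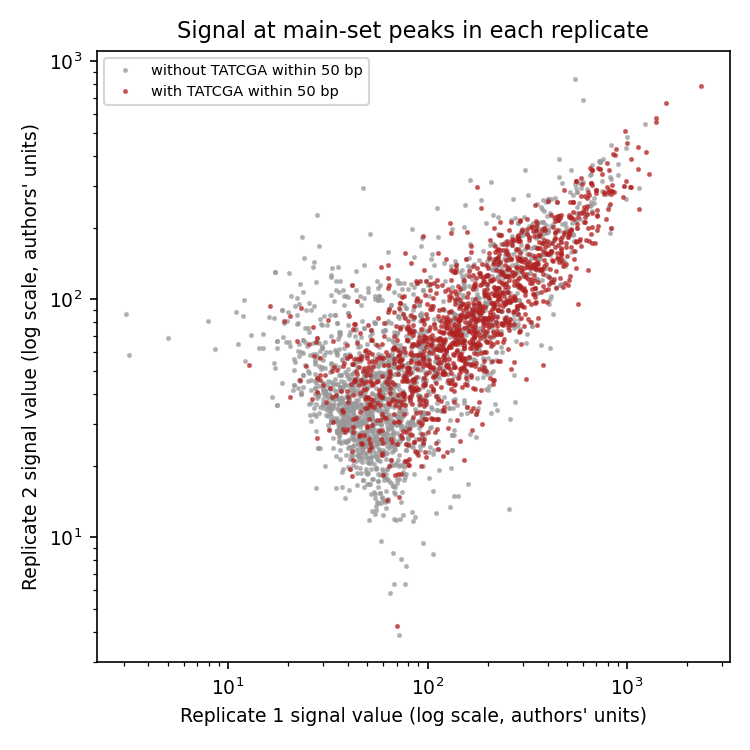
Each point is a main-set peak on the arms with an overlapping peak in both replicates' ranked lists (3290 peaks). The axes give the authors' signal value in replicate 1 and replicate 2 on log scales, and red points have the word TATCGA within 50 bp of the summit. Across these peaks rho was 0.692.

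Where the sites lay relative to genes was asked next. Promoters held 2912 of the 3393 summits (85.8%), against 20.3% for random positions (two-sided permutation p = 0.002, the smallest that 1000 placements can give). The share was 91.8% in replicate 1 alone and 87.6% in replicate 2 alone. A TSS lay within 100 bp of 59.1% of summits, and 73.0% of the promoter summits lay upstream of the nearest TSS. Introns held 5.81% of summits against 36.0% of random positions, intergenic regions 5.66% against 28.8%, and coding exons 1.80% against 11.2%. The promoter share fell with signal, from 98.2% in the fifth of peaks with the highest signal to 69.5% in the fifth with the lowest. Among ranked peaks that did not pass the threshold, the share was 22.7%.

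The genes with the most summits were EcR, the ecdysone receptor, with 9 in 81.2 kb on 2R, hop, the Janus kinase of the fly, with 7 on X, and p (pink) with 6 on 3R. Another 10 genes had 5 summits each, of which CG2889 and CG8036 came first by name. The strongest summit of EcR ranked 1636 by signal and that of hop ranked 441. These counts took every summit in the gene or within 2 kb, whichever TSS was nearest, and counted overlapping peaks separately. The genes p and CG8036 overlap, so the same summit can count for both.

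Which gene groups held summits was tested with lists matched on gene length. Of all 13945 protein-coding genes, 5261 (37.7%) had a summit in the gene or within 2 kb. Ribosomal protein genes had the clearest excess, with 63 of 92 genes (68.5%) against 28.7 expected (adjusted permutation p = 0.0021, from the smallest p that 10000 random lists can give). RpL32 and RpS2 had signals of 2224 and 1303 near their own TSS. The summit of 1489 in the territory of RpS13 lay nearest the TSS of Pp2A-29B. Chemoreceptor genes, which act in sensory neurons, had a summit in 18 of 179 cases against 66.0 expected (adjusted permutation p = 0.0021). The strongest of these, at Ir93a, Or9a and Ir76a, lay nearest the TSS of RpS30, Neb-cGP and Ccdc58. With summits counted only within 1 kb of a gene's own TSS, 4 chemoreceptor genes and 53 ribosomal protein genes were counted. Homeobox genes outside the Hox and segmentation lists had a summit in 8 of 36 cases against 17.2 expected (adjusted permutation p = 0.011). Among them, ey and exd had summits 774 bp and 108 bp from their own TSS, with signals of 671 and 194, and the summit of 402 at tin lay nearest mod(mdg4). The peak at exd overlapped a listed peak of replicate 1 only. The ratio to expectation, 0.465, was 0.492 with summits counted within 1 kb of a TSS (adjusted permutation p = 0.21) and 0.589 with Fisher's exact test (adjusted p = 0.12). It was 0.744 with the nearest TSS (adjusted permutation p = 0.66) and 0.723 in the lower 50% of peaks by signal (adjusted permutation p = 0.94).

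**Figure D2:**
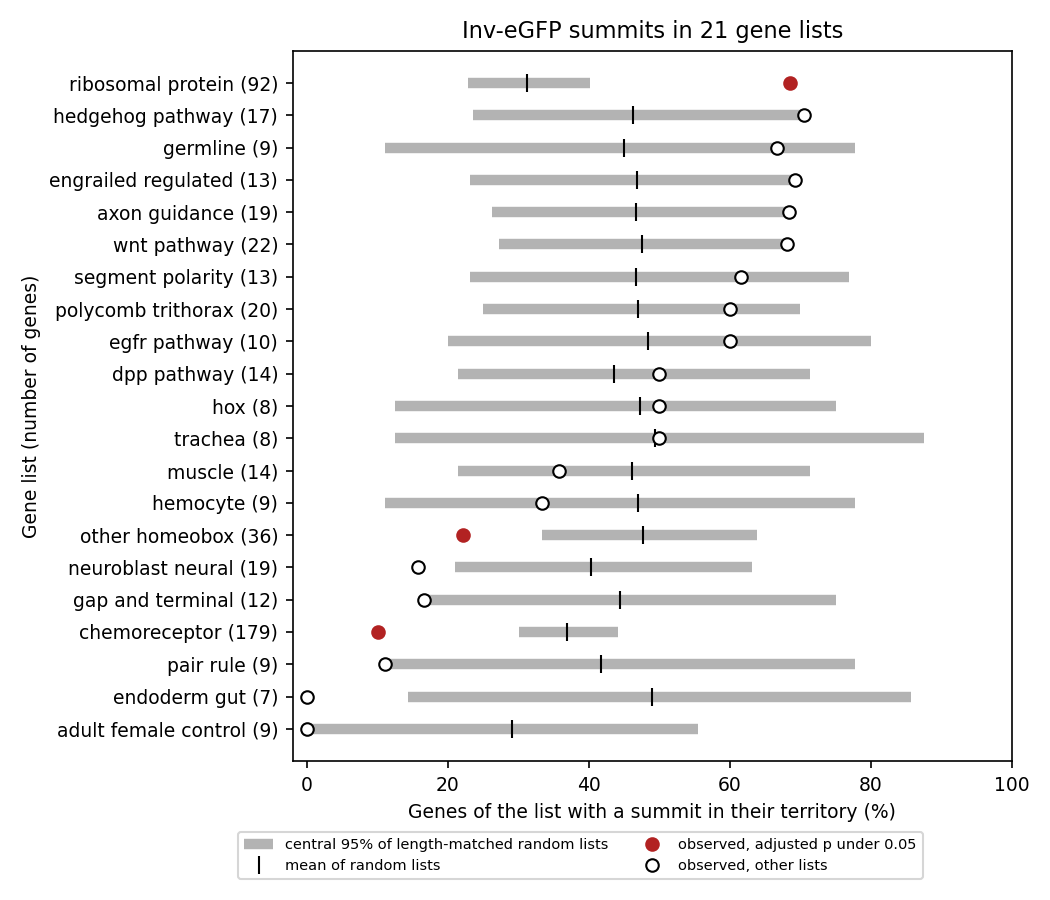
For each of 21 gene lists, the circle gives the percentage of genes with a main-set summit in the gene or within 2 kb, the tick gives the mean of length-matched random lists and the grey bar their central 95%. Ribosomal protein genes (68.5%) lie above their bar, and chemoreceptor (10.1%) and other homeobox genes (22.2%) lie below theirs. Neuroblast and endoderm genes also lie below theirs and did not pass after adjustment.

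Segment polarity genes and genes known from earlier work to be regulated by Engrailed were the lists closest to the tagged factor. Segment polarity genes had a summit in 8 of 13 cases against 6.07 expected (adjusted permutation p = 0.60), and Engrailed-regulated genes in 9 of 13 against 6.09 (adjusted permutation p = 0.31). Neither excess passed the test. Both lists contain en, inv, hh, ptc, ci, wg and slp1, so the counts are not independent. They also include the tagged gene inv and its neighbour en, where extra copies in the transgene could not be decided. Near their own TSS, the T-box genes H15 and mid had signals of 156 and 137, nkd, an inhibitor of Wingless signalling, had 94.0, and ptc, the Hedgehog receptor, had 88.3. The axon guidance receptor gene fra had 617 at its own TSS, and the Polycomb group genes ph-p and ph-d had 206 and 86.7. The only summit of hh, with a signal of 279, lay 13914 bp from the TSS of hh and nearest the TSS of CG31457, and the strongest of Ubx lay nearest modSP. The summit assigned to ci, at 69.9, lay nearest PlexB. The strongest peaks at ptc and ci overlapped no listed peak of either replicate. Those at H15 and nkd overlapped a listed peak of replicate 1 only, and that at ph-d one of replicate 2 only. No main-set summit lay at wg, gsb, gsb-n, slp1, slp2, dpp or Con.

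None of the other lists passed the length-matched test. Hedgehog pathway genes had a summit in 12 of 17 cases (adjusted permutation p = 0.20), with signals of 896 at shf, 745 at boi and 341 at smo, nearest the TSS of Coq7, tko and CG17078. Wnt pathway genes had 15 of 22 (adjusted permutation p = 0.20), led by Apc2 (650), Axn (268) and fz3 (242), of which fz3 was nearest its own TSS. Axon guidance genes had 13 of 19 (adjusted permutation p = 0.20), led by Nrg (1047), fra and PlexB (551). With Fisher's exact test, which does not match length, the Hedgehog, Wnt and axon guidance lists passed (adjusted p = 0.041 for each). In the Polycomb and Trithorax list 12 of 20 genes had one (adjusted permutation p = 0.53), with 618 at Asx, 361 at Pc and 355 at Su(z)12. With the nearest TSS, that list had 13 of 20 genes against 5.64 expected (adjusted permutation p = 0.013). Dpp pathway genes had 7 of 14 (adjusted permutation p = 0.90), with 369 at tkv, 367 at Mad and 301 at gbb, and EGFR pathway genes had 6 of 10 (adjusted permutation p = 0.79), with 816 at S, 156 at spi and 142 at sty. Germline genes had 6 of 9 (adjusted permutation p = 0.53), with 763 at piwi, 319 at tud and 302 at vas. The summits at Mad, gbb, S, piwi and vas lay nearest the TSS of toc, eIF6, ast, TTLL4A and vig. The strongest peaks at spi, tud and vas overlapped a listed peak of replicate 1 only.

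Pair-rule genes had a summit in 1 of 9 cases (3.75 expected; odd, 72.9; adjusted permutation p = 0.22) and gap and terminal genes in 2 of 12 (5.33 expected; oc, 77.4, and gt, 74.5; adjusted permutation p = 0.20). Gap and terminal genes had 0 of 12 in replicate 1 alone, in replicate 2 alone and in the upper 50% of peaks by signal, and 1 of 12 in the conservative list (adjusted permutation p = 0.018, 0.11, 0.13 and 0.15). Neuroblast genes had 3 of 19 (7.66 expected; grh, 131, SoxN, 82.8, and pros, 62.7; adjusted permutation p = 0.18), and 0 of 19 in the upper 50% of peaks by signal (adjusted permutation p = 0.034). The Polycomb and Trithorax, gap and terminal, neuroblast, Hedgehog, Wnt and axon guidance lists each passed in 1 of 9 alternatives, the one named for it here. The peaks at odd, oc, gt and pros overlapped no listed peak of either replicate. Endoderm genes had 0 of 7 (adjusted permutation p = 0.087) and yolk and chorion genes, expressed in adult females, had 0 of 9 (adjusted permutation p = 0.20). Hox genes had 4 of 8 (3.78 expected; abd-A, 141, Ubx, 128, and lab, 123; adjusted permutation p = 1) and tracheal genes 4 of 8 (3.96 expected; trh, 106, bnl, 95.8, and rib, 89.4; adjusted permutation p = 1). Muscle genes had 5 of 14 (Mef2, 304, Tm1, 132, and twi, 95.4; adjusted permutation p = 0.78), and hemocyte genes had 3 of 9 (vkg, 245, Pxn, 113, and ush, 107; adjusted permutation p = 0.78). The summits at pros, bnl, Tm1, twi, vkg, Pxn and ush lay nearest the TSS of mRpL40, Acsx4, MRG15, CG9896, SelT, MEP-1 and lwr. The strongest peaks at lab, trh, bnl and rib overlapped a listed peak of replicate 2 only. Those at abd-A, Ubx, SoxN, Tm1, Pxn and ush overlapped one of replicate 1 only.

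Whether the summits carried the core site of Engrailed-class homeodomains was tested next. TAATTA lay within 50 bp of 4.98% of summits and in 5.38% of flanking windows, a fold of 0.926 (95% block bootstrap interval 0.778 to 1.11; adjusted p = 0.60, exact McNemar test). It ranked 13 of 14 words of its base composition. The TAATTA fold was 1.43 in the fifth of peaks with the highest signal, 1.28 in the upper 50% and 0.650 in the lower 50% (adjusted p = 0.11, 0.17 and 0.0067, exact McNemar test). TATCGA, part of the DNA replication-related element found at many housekeeping promoters, lay at 39.0% of summits against 3.74% of flanks, a fold of 10.4 (9.17 to 11.9; adjusted p = 2.4e-275, exact McNemar test). In replicate 1 alone its fold was 11.1 and in replicate 2 alone 12.1. TATCGA lay at 11 of the 15 strongest shared peaks. The E-box word CAGCTG had a fold of 1.41 and the GATA word AGATAA a fold of 0.694 (adjusted p = 0.0018 for each, exact McNemar test). Both kept their direction but did not pass in replicate 2 alone (folds of 1.21 and 0.864) or in the upper 50% of peaks by signal (1.31 and 0.804). CAGCTG also did not pass more than 1 kb from a TSS (fold 1.17). AGATAA also did not pass in the conservative list (fold 0.814, adjusted p = 0.073, exact McNemar test). The words TAATTG, TGATTA, GAGAGA, CAGGTA, CACGTG and TGACGT had folds of 0.913, 0.886, 0.855, 0.868, 1.23 and 1.01, none past the threshold at all summits. Each word was also ranked by fold among words of its own base composition. GAGAGA, though below its flanks, ranked 1 of 20. TATCGA, CAGCTG and CACGTG ranked 1, 13 and 23 of 102, and AGATAA ranked 30 of 30. TAATTG and TGATTA ranked 49 and 53 of 60, and CAGGTA and TGACGT 114 and 93 of 180. At the 481 summits more than 1 kb from a TSS, TATCGA had a fold of 2.32 and CACGTG one of 3.50 (adjusted p = 0.0018 and 0.010, exact McNemar test). CACGTG, which passed in no other setting, lay at 2.91% of these 481 summits against 0.832% of their flanks. The AT-rich words fell at these 481 summits, TAATTA to 0.557, TAATTG to 0.586, TGATTA to 0.587 and AGATAA to 0.306 (adjusted p = 0.022, 0.041, 0.010 and 0.00098, exact McNemar test). The median fold of the other words of the composition of TAATTA was 0.615 at these summits and 1.15 at all summits.

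**Figure D3:**
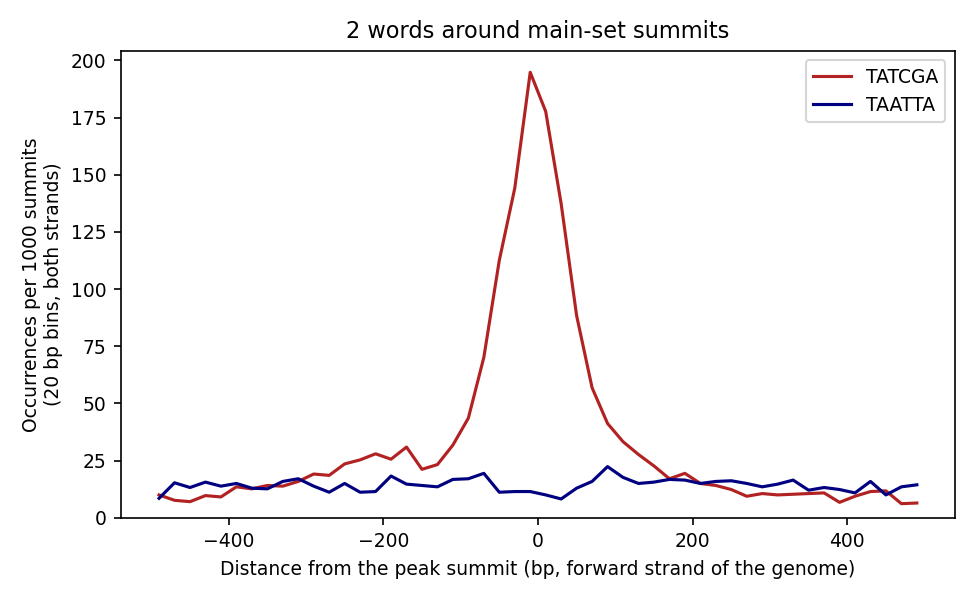
The lines give the number of occurrences of TATCGA (red) and TAATTA (blue) per 1000 main-set summits in bins of 20 bp up to 500 bp on either side, counted on both strands. Of the TATCGA occurrences, 45.5% lie within 50 bp of the summit, against 7.82% of the TAATTA occurrences and 10.1% for an even spread.

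The tagged gene inv and its neighbour en were examined together, at 2R 11454465 to 11548210. This region of 93.7 kb held 9 main-set summits against 2.62 by chance (one-sided permutation p = 0.001). Some of the 9 came from overlapping peaks. With 1 summit per merged region the count was 7 against 2.39 (one-sided permutation p = 0.01). The placements moved each summit on its own, so these p-values take no account of clustering of summits. The strongest, at 2R 11527974 to 11528397, lay 24 bp from the TSS of en, had a signal of 140 and ranked 1630 in the main set. It was the 1 summit of the region that overlapped peaks of both replicates. Counting that one, 2 of the 9 overlapped a listed peak of replicate 1 and 3 one of replicate 2. The rest overlapped a listed peak of neither, as did 531 of 3393 peaks in the main set. The strongest near inv, at 2R 11475365 to 11475788, lay 131 bp from a TSS of inv with a signal of 105 and overlapped a peak of replicate 1. Of the 9 summits 3 lay at promoters, 1 in a coding exon of en and the others between genes. The count was close to chance in the conservative list (2 summits against 1.88, permutation p = 0.56) and in replicate 1 alone (2 against 2.05). It lay above chance without passing the threshold in replicate 2 alone (4 against 1.77, permutation p = 0.10) and without flanks (4 against 1.53, permutation p = 0.073). Of the 9 summits, 8 belonged to the lower 50% of peaks by signal (1.36 expected, permutation p = 0.001).

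**Figure D4:**
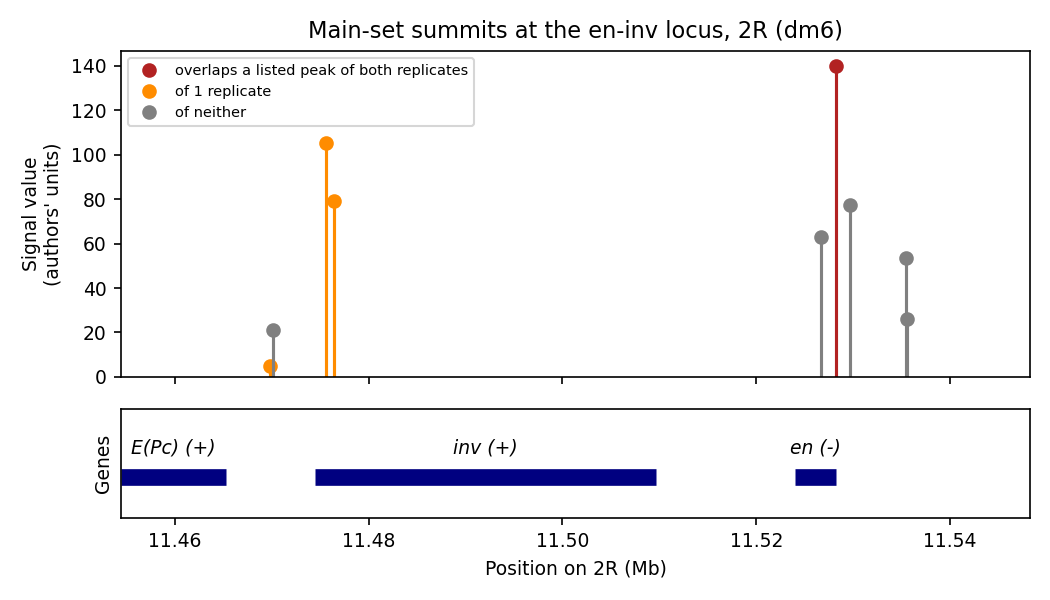
Each stem is a main-set summit at the en-inv locus, with position on 2R (Mb, dm6) on the horizontal axis and the authors' signal value on the vertical axis. Colours give how many replicates' own lists hold an overlapping peak, and bars below give the genes with their strand. The summit of 140 at en is the tallest.

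Summits were spread over all arms, with 27.0 per Mb on X, 27.8 on 2R, 25.6 on 2L, 24.6 on 3R, 22.6 on 3L and 20.8 on chromosome 4. The density on X was 1.08 times that of the autosomes (exact binomial p = 0.079; 95% block bootstrap interval 0.885 to 1.29). It was 1.33 times in the upper 50% of peaks by signal (exact binomial p = 1.9e-06; interval 1.06 to 1.69).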

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

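Main-set peaks outside the 6 chromosome arms, which none of the comparisons used, numbered 13 on 12 other sequences. The conservative list had 5 such peaks, replicate 1 had 1 and replicate 2 had 27. No explanation was tested for them.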

How the results depend on the processing

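The depth of the libraries is unknown, so its effect could not be examined. Merged regions, except for peak numbers, and the lower 50% by signal were chosen after the data were seen. The causes of the changes listed here were not tested. The replicate overlap and the promoter share kept their direction and passed under every alternative run. So did the excess of TATCGA, at folds from 2.32 away from promoters and 5.07 in the lower 50% by signal to 16.0 in the upper 50%. Without each replicate in turn, peak numbers were 2156 to 2859. Summits within 100 bp gave a rho of 0.765. Fisher's exact test, which does not match length, called 5 lists against 3: Hedgehog, Wnt and axon guidance were gained and other homeobox was lost. The TAATTA fold was 1.14 in the conservative list, 1.28 in the upper 50% by signal, 1.15 within 100 bp and 1.02 to 1.26 without each replicate, none past the threshold. It fell below the flanks past the threshold in the lower 50% by signal (0.650) and away from promoters (0.557). The locus had 2 summits in the conservative list, 1 in the upper 50% by signal, 4 without flanks (1.53 expected) and 2 to 4 without each replicate (2.05 and 1.77 expected), none past the threshold, and it passed with 7 in merged regions and 8 in the lower 50% by signal. The X ratio passed the binomial threshold at 1.23 in the conservative list, 1.33 in the upper 50% by signal and 1.13 to 1.16 without each replicate, but its block bootstrap interval lay above 1 only in the upper 50%. Of 189 values for single lists, 164 kept direction and side. Ratios that crossed 1 were segment polarity (0.998, conservative; 0.944 to 1.06 without each replicate), EGFR (0.902 to 1.37), Hox (0.451, upper 50%; 0.390 to 0.589; 0.812, TSS), trachea (0.304, conservative; 0, upper 50%; 0.541 to 1.06; 0.677, TSS) and, in the lower 50%, Dpp (0.882), Polycomb (0.994), muscle (1.30) and germline (0.982). Of 81 values for other words, 66 kept both. Folds that crossed 1 were TAATTG (1.04, 100 bp), TGATTA (1.02, upper 50%; 0.937 to 1.03), GAGAGA (1.29) and CAGGTA (1.65) away from promoters, and TGACGT (0.877, lower 50%). No paired analysis was possible because there was 1 group.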

Other observations

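Other gene families, chosen after the strongest genes had been seen, were tested in the same way with adjustment over these 8 families. Mitochondrial ribosome genes had a summit in 48 of 73 cases against 19.2 expected (adjusted permutation p = 0.0008), with signals of 984 at mRpL4, 948 at mRpL17 and 840 at mRpL19. Proteasome genes had 28 of 48 against 15.8 (adjusted permutation p = 0.0011), led by Rpn6 (1930), Prosalpha7 (903) and Rpn10 (858). Translation initiation genes had 26 of 44 against 17.3 (adjusted permutation p = 0.022), led by eIF3c (1104), eIF3f1 (931) and eIF2gamma (773). The summits at mRpL17, mRpL19 and eIF2gamma lay nearest the TSS of Tudor-SN, Unc50 and Set. Cuticle genes had fewer, 7 of 70 against 21.6 (adjusted permutation p = 0.0008), and the summit of 372 at Cpr73D lay nearest Ogdh. Complex I genes (17 of 40), tRNA synthetase genes (17 of 32), replication licensing genes (8 of 12) and odorant binding protein genes (7 of 51) did not pass (adjusted permutation p = 0.19, 0.35, 0.19 and 0.074).

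Among the explanations weighed here, the test on TAATTA in the fifth with the highest signal was chosen after the result was seen. So were the ratios to words of the same composition and the tests on GGTCAC promoters, on another antigen and on shoulders. The intervals of each replicate's TATCGA fold were also chosen then. At all summits, the TAATTA fold and its McNemar test were fixed before, and the bound on the interval of that fold came after. No difference between groups could serve as a biological explanation, because the design has 1 group. TATCGA lay at 39.0% of summits (58.8% in the upper 50% by signal, 19.3% in the lower 50%), and TAATTA was in no excess over all summits. Binding through TAATTA over the whole set of summits was argued against by its fold of 0.926 (interval 0.778 to 1.11), which is 0.803 of the median of the other words of its composition (interval 0.666 to 0.932). This covers the main set only. The TAATTA fold was 1.14 in the conservative list, 1.02 in replicate 1 alone and 1.26 in replicate 2 alone, none past the threshold. A wrong label on 1 of the libraries as the source of the TATCGA excess was argued against, since it leaves the other library as labelled and both replicates' own lists had the excess, with folds of 11.1 (interval 9.91 to 12.7) and 12.1 (10.2 to 14.2), over the bound of 3 set before for both. These folds do not show that either label is right. Binding through TAATTA at the strongest summits stays open: in the fifth with the highest signal its fold was 1.43 (interval 0.986 to 2.11) and 0.904 of the median of those other words (interval 0.598 to 1.26), and in the upper 50% it was 1.28 and 0.823 of that median (0.631 to 1.03). Away from promoters it stays open too: the fold of 0.557 met the bound set before, but that bound took no account of base composition, and against words of the same composition the ratio was 0.905 (interval 0.529 to 1.53). A background common to housekeeping promoters also stays open: TSS with TATCGA within 150 bp held a summit 1.52 times as often as TSS with GGTCAC, another housekeeping promoter word (interval 1.44 to 1.61, across the bound of 1.5). A reading that was run first, without TSS that carry both words, gave 2.10 (1.92 to 2.31), which goes against it. However, a summit lay at 24.2% of TSS with GGTCAC alone against 15.3% with neither word. The share was 50.9% with TATCGA alone and 63.3% with both words. Another antigen or unspecific antibody signal in both libraries cannot be told apart from binding by Inv-eGFP, since it would give the TATCGA fold of 10.4 in the main set and the excess in each replicate too, and no control immunoprecipitation stands beside them.

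The en-inv locus had more summits than chance in the main set. Extra copies of the locus in the transgene could not be decided: the median signal of its 112 unlisted peaks, 22.6, lay at the 84.7 percentile of 2R windows, between the bounds of 75 and 95 set before. Whether promoter density alone accounts for the excess was not decided. Of 10000 placements of all 2R summits among 2R promoter regions, 0% gave 9 summits, with a highest count of 6, under the bound of 1% set before. That reading set all 9 summits, of which 3 lay at promoters, against placements at promoters only. It also counted summits of overlapping peaks separately, so no conclusion is drawn from it. In a narrower reading that was run first, with the 3 promoter summits alone, 2.79% of placements gave as many, which lies between the bounds of 1 and 5, so it left the question open. The excess lay among weaker peaks: the lower 50% by signal had 8 of the summits, and the conservative list had 2.

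Some listed peaks had a signal below the median of unlisted peaks (19.3). They made up 3.68% of the main set, and 100% of them overlapped a listed peak of higher signal, at a median distance of 204 bp between summits. As a hypothesis, they may be shoulders of a stronger listed peak.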
